A study of Mus musculus with 36 samples.

How the data were processed

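Bulk RNA from mouse hippocampus was measured by RNA sequencing in 36 libraries. They fell into 6 groups of 6 libraries: wild-type (WT), Fmr1 knockout (KO) and Shank3 KO mice, each given vehicle or cannabidiol (CBD). Each group held 3 males and 3 females. Per the labels, mice were injected under the skin for 7 days, and the CBD dose was 5 mg/kg for males but 50 mg/kg for females. Sex and dose therefore could not be separated among treated mice. The animal codes differed for every library, so each library was taken as 1 animal. The codes began with the same letters in 11 of 12 WT and in all 12 Fmr1 KO libraries, with others in the 12 Shank3 KO libraries and with others again in WT CBD replicate 1. No code number was shared between genotypes, and what letters and numbers stand for is not given in the sources used here. Strain, knockout allele, litter and sequencing date are not given in the sources used here.

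The deposited table held raw read counts per gene, with no normalization. Per the submitters' processing notes, reads were checked with FastQC, aligned with STAR 2.7.11b to build GRCm39 and counted with featureCounts 2.0.8. The annotation release, the strand setting and the read filters are not given in the sources used here. The table held 78298 gene identifiers, of which 43981 had at least 1 count. An older mouse annotation gave a symbol to 51498 of them, which held 99.0% of the counts. The same annotation gave chromosomes and gene order. Genes without a symbol there are named by identifier. Total counts per library ran from 11655697 to 33228089. No library was identical to another.

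The gene lengths deposited beside the counts were compared with that annotation. Of 20339 protein-coding genes with introns, 98.1% had a length within 5% of the whole gene span and 0.300% had one within 5% of the joined exons. A count was therefore read as covering the gene body, introns included.

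Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 21172 genes with 99.9% of the counts, and libraries were scaled by TMM. A quasi-likelihood model was fitted to all 36 libraries with 1 coefficient per genotype and treatment group and an additive sex term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. The planned comparisons were each KO against WT under vehicle and under CBD, CBD against vehicle in each genotype, and the difference of the CBD effect between each KO and WT. A second model with 1 coefficient per genotype, treatment and sex gave the CBD effect per sex and the sex difference under vehicle. These comparisons, the gene lists, the rule for named genes and most alternative settings were chosen before the data were examined. The mean CBD effect over the 3 genotypes, that mean per sex, the direct comparison of the KO lines and the genotype comparisons per sex were added after seeing the data.

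Log2 fold changes are edgeR's, with its default prior count. Each standard error (SE) came from the information matrix of the fitted model, scaled by the moderated quasi-likelihood variance. This SE was adopted after the values per sex had been seen, in place of the fold change divided by the root of the F statistic, which was off for genes with few counts. Fold changes, p-values and calls did not depend on that choice. No estimate is given where a group in the contrast had no count. Levels are CPM, counts scaled to library size, with SD over the 6 libraries of a group. All tests were two-sided.

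The 46 gene lists, 19 of them of cell type or tissue markers, held 995 entries. They were tested with camera in limma 3.58.1 on voom values at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Camera compares a list with the other genes, whereas fry tests a list alone. A list needed 3 measured members, and p-values were adjusted over the lists within a comparison. A list of 20 neutrophil genes was written after the mean CBD effect had been seen.

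The genes named by rule were the targeted genes, the 12 called genes with the smallest p in each direction and the 3 members with the smallest p of each list past the threshold. Symbols of predicted genes were left out of the first part. Where fewer than 5 genes were called, the 5 with the smallest p were given as values. In the difference and per-sex contrasts the rule took 5 called genes in each direction. Cnr1, Gpr55, Oxtr, Grm5 and Bdnf were named in every main comparison. Called genes without a symbol were named after their values were seen.

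The alternatives were DESeq2 size factors in edgeR, no filter beyond a total of 1 count, a strict filter of 10 counts in 30 libraries, the Wald test of DESeq2 1.42.0 and limma voom with sample quality weights. Others were no sex term, the replicate number as a block, 1 surrogate variable from sva 3.50.0, the compared groups alone, and leaving out each library in turn or the 3 libraries farthest out on principal components of 2000 genes. Covariates of tissue markers or of erythrocyte markers, and gene lists without each library, were added after seeing the data. A covariate of Y-linked counts was planned only if sex was not given, and was not needed. For each count of calls, 100 splits of the libraries were drawn with a fixed seed. For values that share control libraries, the shared group was divided between the comparisons. In addition, 40 datasets were simulated in which only the called genes differed by genotype and none changed with CBD.

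The pipeline was tested on simulated data in which 100 genes were changed 1.5-fold and 100 genes 2-fold. Run on 20850 genes for CBD and on 20890 for genotype, edgeR called 36% to 42% of the former and 54% to 77% of the latter, with 1 to 10 calls on unchanged genes. A set of 30 genes shifted 1.2-fold gave a camera p of 7.52e-18. The median SE of a log2 fold change was 0.180 to 0.181 in the 5 main comparisons and 0.104 for the mean CBD effect.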

Results

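Hippocampal gene expression was compared between WT, Fmr1 KO and Shank3 KO mice given vehicle or CBD, with 6 animals in each of 6 groups. Fmr1 encodes the RNA-binding protein FMRP, whose loss causes fragile X syndrome, and Shank3 encodes a postsynaptic scaffold linked to autism. CBD is a plant cannabinoid without the intoxicating action of tetrahydrocannabinol. Total counts averaged 24788829 in WT vehicle, 26038686 in WT CBD, 26974594 in Fmr1 KO vehicle, 27978461 in Fmr1 KO CBD, 26126956 in Shank3 KO vehicle and 27118116 in Shank3 KO CBD libraries. Shank3 KO vehicle replicate 2 had the lowest total, 11655697, and the others ran up to 33228089. Principal components of the libraries held 25.5%, 15.7% and 8.7% of the variance. They followed the mean levels of cell type and tissue markers. Component 1 correlated most strongly with markers of choroid plexus (r = 0.84), CA1 (-0.73) and thalamus (0.71). Component 2 did so with CA3 (-0.71) and dentate neurons (-0.68), and component 3 with myelin (-0.56) and interneurons (0.56). Libraries therefore differed in their make-up of tissue markers, whose source was not tested.

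Each targeted gene was lower in its own KO line. Fmr1 stood at 41.1 ± 2.89 CPM (SD, n = 6) in Fmr1 KO vehicle mice against 73.9 ± 4.86 in WT vehicle mice and 73.8 ± 4.28 in Shank3 KO vehicle mice. Shank3 stood at 168 ± 8.75 CPM in Shank3 KO vehicle mice against 265 ± 19.5 in WT vehicle mice (SD, n = 6). With CBD, Shank3 was at 176 ± 22.7 CPM in Shank3 KO mice. Counts covered whole gene bodies, introns included, so the counts left in a KO line do not measure intact messenger.

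**Figure D1:**
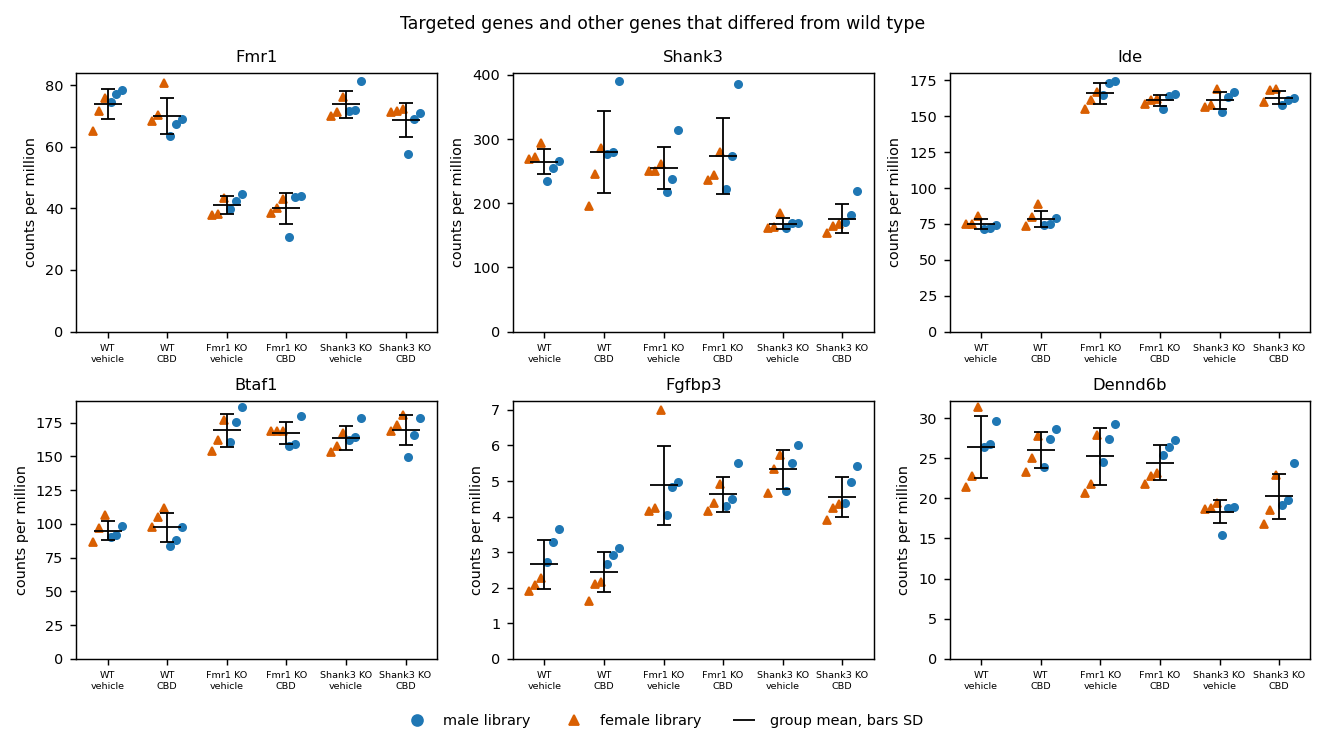
Level of Fmr1 and Shank3 in CPM for each library, by group (n = 6), with the mean and SD. Fmr1 averaged 41.1 in Fmr1 KO vehicle mice against 73.9 in WT vehicle mice, and Shank3 averaged 168 in Shank3 KO vehicle mice against 265 in WT vehicle mice.

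Fmr1 KO against WT mice under vehicle asked what loss of FMRP changes in the hippocampus. Besides Fmr1 itself (log2 fold change -0.85, SE 0.0752, adjusted p = 4.87e-09), the called genes were all higher in the KO. Ide, which encodes a protease that degrades insulin and amyloid beta, rose by 1.15 (SE 0.0480, adjusted p = 5.90e-18). Btaf1, a regulator of the TATA-binding protein, rose by 0.83 (SE 0.0660, adjusted p = 3.02e-10), and Fgfbp3, a carrier of fibroblast growth factors, by 0.90 (SE 0.142, adjusted p = 0.00161). The identifiers ENSMUSG00000120174 and ENSMUSG00000131195, which have no symbol here, rose by 3.03 (SE 0.218, adjusted p = 2.01e-11) and 2.89 (SE 0.576, adjusted p = 0.00350). These were 5 genes higher and 1 lower, with 475 genes at an unadjusted p under 0.05. With no change at all, a share of about 0.05 of the 21172 tested genes would have such p-values. Here the share was 2.24%, and it was 2.64% to 5.63% in the other main comparisons. Over all contrasts it ran from 1.16% to 8.50%, so these counts alone are not read as changes. DESeq2 and limma voom called 6 genes each. Fitted on the 12 compared libraries alone, 4 genes were called. Fgfbp3 kept its fold (0.90) but not its call (adjusted p = 1), and ENSMUSG00000131195 had no value in that fit.

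Protein-folding genes had slightly lower values in Fmr1 KO vehicle mice. Of 22 measured genes of the unfolded protein response, 20 had lower values (median -0.10, camera adjusted p = 0.000199; adjusted p = 0.997 with an estimated correlation), among them Pdia6 (-0.21), Creld2 (-0.25) and Manf (-0.19), which act in the endoplasmic reticulum. Of 17 heat shock genes, 16 had lower values (median -0.09, adjusted p = 0.00427; adjusted p = 0.997 with an estimated correlation), among them the chaperone genes Hsph1 (-0.12), Hspb1 (-0.45) and Hspa1a (-0.28). Adjusted over the list alone, 0 genes of either list passed in edgeR. Without Fmr1 KO vehicle replicate 4 the unfolded protein list was not called (-0.06, 0.0618), and its median was -0.05 without WT vehicle replicate 6. The heat shock call was lost without Fmr1 KO vehicle replicate 4 (-0.05, 0.156) and without WT vehicle replicate 4 (-0.03, 0.151) or 1 (-0.04, 0.0865). Its median was also -0.05 without WT vehicle replicate 2, -0.04 without Fmr1 KO vehicle replicate 2 and -0.14 without WT vehicle replicate 3 or 6. No other list passed, including the known messenger targets of FMRP.

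Ide, Btaf1 and Fgfbp3 lie close together on chromosome 19. In gene order, Btaf1 lies 3 and Fgfbp3 4 protein-coding genes from Ide. Ide ran from 71.3 to 88.7 CPM in the 12 WT libraries and from 153 to 175 in the 24 KO libraries of both lines. Btaf1 ran from 83.7 to 112 CPM against 150 to 186, and Fgfbp3 from 1.63 to 3.65 against 3.91 to 7.00. No other gene of the segment passed. Under vehicle Cpeb3 was at 0.08 in Fmr1 KO and 0.09 in Shank3 KO mice, March5 at -0.02 and -0.07, Tnks2 at 0.02 and -0.02, and the low-count gene Kif11 at 0.23 and 0.49 (adjusted p = 0.853 in Shank3 KO mice). ENSMUSG00000120174 ran from 0.0797 to 0.621 CPM in WT and from 2.84 to 5.95 in KO libraries. The position of that identifier is not given in the annotation used here.

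**Figure D2:**
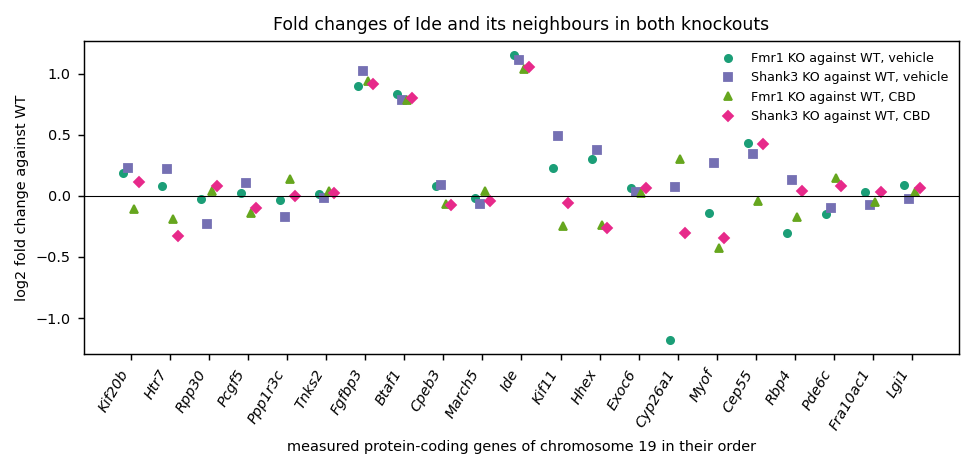
Log2 fold change of each KO line against WT for protein-coding genes around Ide on chromosome 19, in gene order. Ide, Btaf1 and Fgfbp3 were higher in both lines, at 1.15, 0.83 and 0.90 in Fmr1 KO vehicle mice, and no other gene shown was called. The low-count gene Cyp26a1 lay at -1.18 in Fmr1 KO and 0.08 in Shank3 KO vehicle mice.

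Shank3 KO against WT mice under vehicle asked the same of the scaffold. Shank3 fell by 0.66 (SE 0.118, adjusted p = 0.0103). Dennd6b, which encodes an activator of Rab GTPases and lies 18 protein-coding genes from Shank3 on chromosome 15, fell by 0.52 (SE 0.0938, adjusted p = 0.0103). ENSMUSG00000139902 fell by 1.47 (SE 0.243, adjusted p = 0.00342). The genes that rose were Ide (1.11, SE 0.0480, adjusted p = 1.94e-17), Btaf1 (0.79, SE 0.0660, adjusted p = 1.43e-09), Fgfbp3 (1.02, SE 0.142, adjusted p = 0.000180), ENSMUSG00000120174 (3.22, adjusted p = 3.82e-12) and ENSMUSG00000131195 (3.29, adjusted p = 0.000229). The count was 5 higher and 3 lower, with 1193 genes at an unadjusted p under 0.05, 12 calls by DESeq2 and 8 by limma voom. The unadjusted count was 758 without WT vehicle replicate 4 and 732 without Shank3 KO vehicle replicate 2. With tissue marker covariates, Shank3 (-0.58, adjusted p = 0.0946) and Dennd6b (-0.49, adjusted p = 0.0620) lost their calls while their folds stayed close. Dennd6b was also lost in the compared groups alone (-0.52, 0.269), without WT vehicle replicate 6 (0.0841) and without Shank3 KO vehicle replicate 2 (0.0645).

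Markers of striatum were higher in some Shank3 KO vehicle libraries. As a list all 12 had higher values (median 1.76, camera adjusted p = 2.48e-05; adjusted p = 0.928 with an estimated correlation), and 11 passed when adjusted over the list alone. The score of these markers was 5.77, 4.81 and 4.0 in replicates 2, 3 and 4 but 2.22, 1.76 and 1.92 in replicates 1, 5 and 6, near the 1.61 to 2.5 of WT vehicle mice. Without replicate 2 the median was 1.08. The adenosine receptor gene Adora2a was at 3.15 (SE 0.961) and the dopamine receptor gene Drd2 at 2.96 (SE 1.03). All 13 ependymal genes were higher (median 0.52, camera adjusted p = 0.000555; adjusted p = 0.928 with an estimated correlation), a call kept without each of the 12 compared libraries. The choroid plexus, oligodendrocyte and mural cell lists were called higher too, but in 6, 5 and 6 of 12 fits without a library, and the endothelial list in 9 of 12, with an adjusted p = 0.928 with an estimated correlation for each. Higd1b, a pericyte gene, was at 0.66 with an unadjusted p of 0.00409.

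Markers of dentate gyrus granule neurons were lower in the same mice, in 13 of 14 genes (median -0.40, camera adjusted p = 7.04e-05; adjusted p = 0.928 with an estimated correlation), and 1 passed when adjusted over the list alone. Plk5, at 6.86 ± 1.34 CPM against 12.5 in WT vehicle mice, was at -0.86 (SE 0.247). Fat4 (-0.30) and C1ql2 (-0.88) followed. Ribosomal protein genes were lower in 64 of 69 (median -0.11, adjusted p = 6.34e-05; adjusted p = 0.928 with an estimated correlation), with Rpl5 at -0.16 and Rpl4 at -0.19. Of 26 listed neighbours of Shank3 on chromosome 15, 21 were lower (median -0.10, adjusted p = 0.00825; adjusted p = 0.928 with an estimated correlation), and Dennd6b alone was called. The nearest genes did not fall together: of 15 tested within 12 protein-coding genes of Shank3, 7 were lower and 8 higher, among them Odf3b (0.75), Lrrk2 (0.53), Rabl2 (0.19) and Cpne8 (0.17). Without WT vehicle replicate 4 the ribosomal call was lost (-0.06, 0.0636), and without Shank3 KO vehicle replicate 2 that of the neighbours (0.0803) and the ribosomal median was -0.07.

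Both KO lines were compared with the same WT vehicle libraries, which alone can make their fold changes alike. The 5 genes higher in both lines were Ide, Btaf1, Fgfbp3, ENSMUSG00000120174 and ENSMUSG00000131195. Independent lists would share 0.00118 higher genes, no simulated dataset shared any, and 3 or 4 genes were shared with the WT vehicle libraries divided between the comparisons. Over the other 21163 genes the fold changes correlated at r = 0.426, against 0.476 to 0.523 in 40 simulated datasets without changes. With divided WT libraries the mean was -0.0675. The simulated datasets drew each gene independently, so their range can be too narrow. Genes are not independent replicates in such a correlation. Compared directly, Fmr1 KO and Shank3 KO vehicle mice differed in Fmr1 (-0.84, adjusted p = 2.09e-08) and ENSMUSG00000139902 (1.37, adjusted p = 0.0317), with 1054 genes at an unadjusted p under 0.05.

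CBD against vehicle in WT mice asked what the compound changes without a mutation. No gene passed in edgeR (smallest adjusted p = 0.721), with 567 genes at an unadjusted p under 0.05, and DESeq2 and limma voom called 0 each. Without WT CBD replicate 1 the unadjusted count was 1477. The smallest p-values belonged to Lcn2, an iron-binding protein of the acute-phase response (2.46, SE 0.543), Vwf, the von Willebrand factor made by endothelium (0.85, SE 0.186), Ms4a6d (1.08), growth hormone, Gh (-7.58), and ENSMUSG00000123200 (0.95). Lists of blood vessel cells were higher as sets, and choroid plexus genes, not called (adjusted p = 0.262), had higher values in 17 of 17 (median 0.58). The choroid plexus score averaged 3.28 in WT CBD against 2.77 in WT vehicle libraries. All 15 endothelial genes had higher values (median 0.29, camera adjusted p = 6.06e-09; adjusted p = 0.225 with an estimated correlation), among them Tek (0.32), Abcb1a (0.40) and Slc2a1 (0.29). So had 11 of 12 mural cell genes (median 0.26, adjusted p = 2.85e-05; adjusted p = 0.225 with an estimated correlation), among them Abcc9 (0.46) and Myh11 (0.46). Adjusted over the list alone, 1 gene passed in each. Both calls were kept without each of the 12 compared libraries, and the endothelial median was 0.19 without WT vehicle replicate 5.

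Immune and hormone-response lists were also higher in WT mice given CBD. The interferon list was higher in 19 of 25 genes (median 0.16, camera adjusted p = 3.16e-05; adjusted p = 0.392 with an estimated correlation), with Trim30a at 0.55, Usp18 at 0.80 and Ifi44 at 0.90, and its median was 0.31 without WT CBD replicate 2. The glucocorticoid list was higher in 21 of 24 (median 0.13, adjusted p = 0.00144; adjusted p = 0.437 with an estimated correlation), with Lcn2 as the gene of smallest p. Its median was 0.07 without WT CBD replicate 5, 0.08 without WT vehicle replicate 6 and 0.07 without WT vehicle replicate 3. Ribosomal protein genes were lower in 68 of 69 (median -0.10, adjusted p = 3.20e-07; adjusted p = 0.862 with an estimated correlation). Their median was -0.05 without WT vehicle replicate 4, -0.15 without WT vehicle replicate 6 or WT CBD replicate 1, and -0.16 without WT vehicle replicate 3. These 3 calls were kept without each of the 12 compared libraries.

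Striatal markers were higher in 2 of the 6 WT CBD libraries. As a list all 12 had higher values (median 1.70, camera adjusted p = 0.00185; adjusted p = 0.862 with an estimated correlation), and 10 passed when adjusted over the list alone. The score was 5.64 in replicate 3 and 4.18 in replicate 6, and 1.56 to 2.32 in the other 4 libraries. Without WT CBD replicate 3 the median was 0.46 and the call was lost (0.433). The antigen presentation and inflammation list, with Icam1 at 0.71, was called higher (adjusted p = 0.00185; adjusted p = 0.862 with an estimated correlation) but not without WT CBD replicate 1 (0.208) or WT vehicle replicate 3 (0.0615). The dentate list was called lower (adjusted p = 0.00837; adjusted p = 0.862 with an estimated correlation) but not without WT CBD replicate 2 (0.476), WT vehicle replicate 5 (0.0771) or 3 (0.0935). Lists called in 7 or fewer of 12 such fits were those of oligodendrocytes, unfolded protein response, oxidative phosphorylation and ependyma, the last with a median and mean of 0.01 although called lower (adjusted p = 0.862 with an estimated correlation for each).

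CBD against vehicle in Fmr1 KO mice asked the same in the fragile X model. No gene passed in edgeR (smallest adjusted p = 0.274, Lcn2 at 3.19, SE 0.716), with 558 genes at an unadjusted p under 0.05, and DESeq2 and limma voom called 0 each. That count was 1083 without Fmr1 KO vehicle replicate 6 and 943 without Fmr1 KO CBD replicate 2. Myelin genes were lower as a set, in 19 of 19 (median -0.45, camera adjusted p = 2.84e-12; adjusted p = 0.814 with an estimated correlation), with Aspa at -0.65, Gjc3 at -0.47 and Ugt8a at -0.51. Fmr1 KO CBD replicate 3 carried much of this, with a myelin score of 3.92 against 5.55 to 6.25 in the other 5, and without it the median was -0.24 (0.000766). Ependymal genes were lower in 11 of 13 (median -0.47, adjusted p = 0.000771; adjusted p = 0.814 with an estimated correlation), and by -0.31 without Fmr1 KO vehicle replicate 1. The CA3 list was called lower (median -0.19, adjusted p = 0.0350; adjusted p = 0.814 with an estimated correlation), but not without Fmr1 KO CBD replicate 3 (-0.12, 0.335) or 6 (0.0721), or Fmr1 KO vehicle replicate 1 (0.0670), 3 (-0.09, 0.252) or 5 (0.0779). The choroid plexus list was called in 5 of 12 such fits (adjusted p = 0.919 with an estimated correlation). Adjusted over the list alone, no gene of these lists passed in edgeR.

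Microglial genes were higher in Fmr1 KO mice given CBD, in 12 of 12 (median 0.17, camera adjusted p = 9.29e-05; adjusted p = 0.814 with an estimated correlation), with the complement gene C1qa at 0.33 and the protease gene Ctss at 0.28. Their median was 0.27 without Fmr1 KO vehicle replicate 6 and 0.10 without Fmr1 KO CBD replicate 5. Ribosomal protein genes were higher in 64 of 69 (median 0.10, adjusted p = 5.62e-06; adjusted p = 0.814 with an estimated correlation), by 0.06, 0.05 and 0.19 without Fmr1 KO vehicle replicates 4, 3 and 6. Heat shock genes were higher in 16 of 17 (median 0.10, adjusted p = 0.000373; adjusted p = 0.814 with an estimated correlation), by 0.07 without Fmr1 KO vehicle replicate 4 or 2. These 3 calls were kept without each of the 12 compared libraries. The early genes, FMRP targets, unfolded protein and oxidative phosphorylation lists were called higher, but in 8, 5, 8 and 7 of 12 such fits (adjusted p = 0.814 with an estimated correlation or more). Apold1, an early gene of endothelium, was at 0.66 with an unadjusted p of 0.00129. Dlgap3, a scaffold messenger bound by FMRP, was at 0.23, and Ddit3, a stress transcription factor, at 0.25.

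CBD against vehicle in Shank3 KO mice gave no call in edgeR (smallest adjusted p = 0.494), with 934 genes at an unadjusted p under 0.05, 0 calls by DESeq2 and 1 by limma voom. Without Shank3 KO CBD replicate 5 the unadjusted count was 609. The gene called by voom, Grm2, encodes a presynaptic glutamate receptor (0.89, SE 0.187). Lcn2 was at 2.59 (SE 0.604), Gm3650 at 1.62, AC138228.2 at 1.07 and Mir487b at -1.16. Dentate granule genes were higher as a set, in 14 of 14 (median 0.43, camera adjusted p = 9.06e-07; adjusted p = 0.538 with an estimated correlation), and 2 passed when adjusted over the list alone. Plk5 was at 0.75, Fat4 at 0.37 and C1ql2 at 0.95. The glucocorticoid list was higher in 18 of 24 (adjusted p = 7.63e-05; adjusted p = 0.538 with an estimated correlation), with Fkbp5 at 0.32 and Arrdc2 at 0.58. Immediate early genes were higher in 28 of 33 (adjusted p = 0.000400; adjusted p = 0.853 with an estimated correlation), with Btg2 at 0.48 and Ier2 at 0.46. These 3 calls were kept without each of the 12 compared libraries. FMRP targets, with Adcy1 at 0.56, were called higher (adjusted p = 0.0111; adjusted p = 0.853 with an estimated correlation) but not without Shank3 KO CBD replicate 6 (0.0710). Postsynaptic scaffolds and the antigen presentation list were called in 9 and 5 of 12 such fits (adjusted p = 0.853 with an estimated correlation).

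Markers of striatum, ependyma and choroid plexus were lower in the same comparison. Striatal markers were lower in 12 of 12 (median -1.14, camera adjusted p = 0.000400; adjusted p = 0.853 with an estimated correlation), with Ppp1r1b at -1.31. Their median was -0.49 without Shank3 KO vehicle replicate 2 and -2.15 without Shank3 KO CBD replicate 2, the libraries with the highest scores of their groups. Ependymal genes were lower in 13 of 13 (median -0.48, adjusted p = 0.000303; adjusted p = 0.853 with an estimated correlation). Choroid plexus genes were lower in 17 of 17 (median -1.09, adjusted p = 0.00174; adjusted p = 0.853 with an estimated correlation), with the water channel gene Aqp1 at -1.47, but not called without Shank3 KO vehicle replicate 5 (0.0788) or Shank3 KO CBD replicate 6 (0.107). The thalamic, myelin and cholesterol synthesis lists were called lower in 7, 8 and 7 of 12 such fits (adjusted p = 0.853 with an estimated correlation), and the thalamic median was 0.07 without Shank3 KO vehicle replicate 1. Of the cholesterol synthesis genes, Hmgcs1 was at -0.29 and Idi1 at -0.26.

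**Figure D3:**
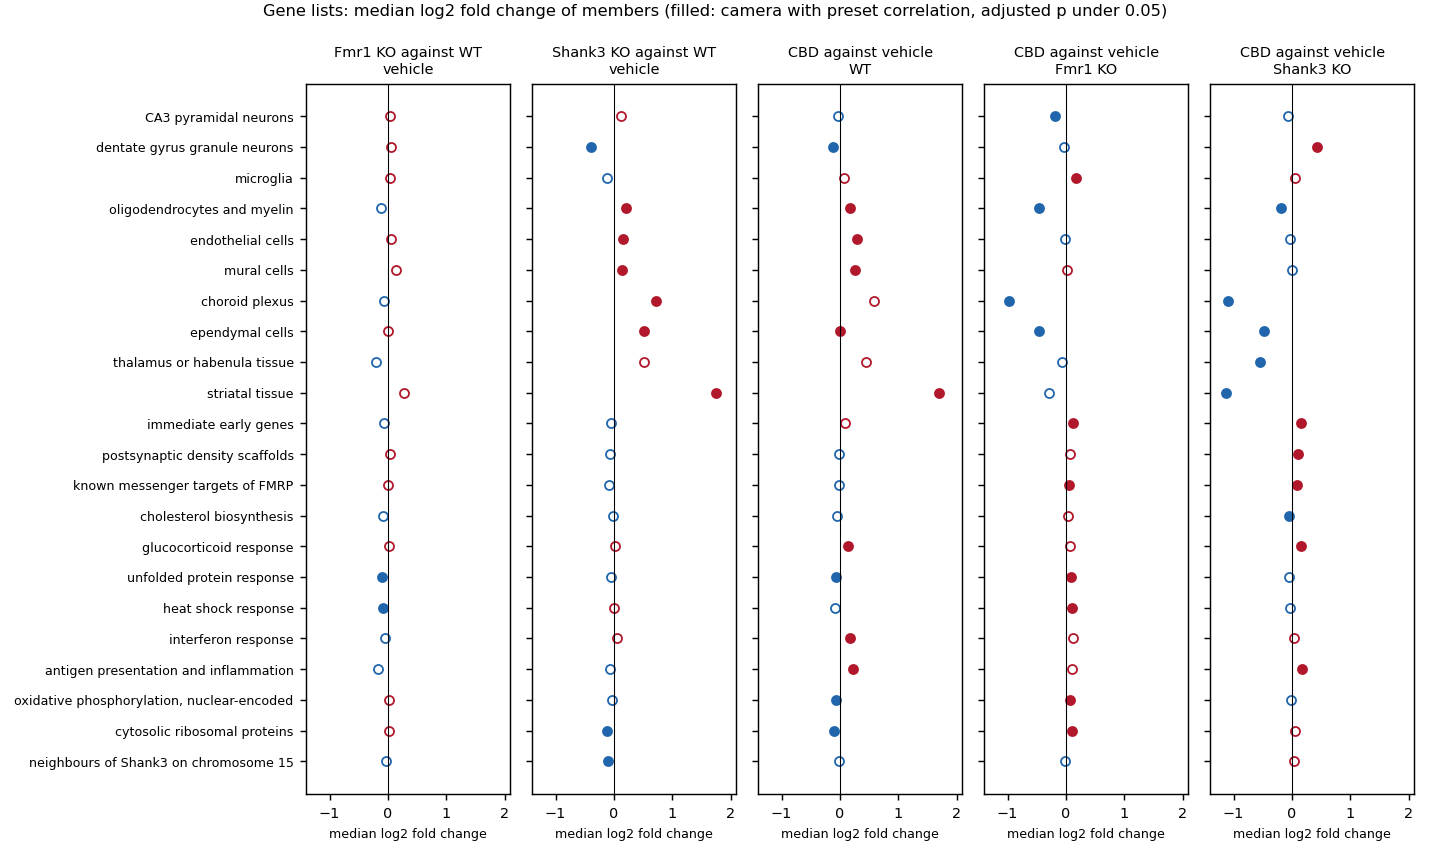
Median log2 fold change of the members of each gene list in the 5 main comparisons, for lists that camera called in at least 1 of them. Filled points mark a camera adjusted p under 0.05 with the preset correlation and colour gives the sign of the median, which for the ependymal list of WT mice given CBD (0.01) was opposite to camera's direction.

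Whether the CBD effect depended on genotype was tested by the difference of the effects. For Fmr1 KO minus WT no gene passed in edgeR (smallest adjusted p = 0.993), with 635 genes at an unadjusted p under 0.05, and for Shank3 KO minus WT none passed (0.912), with 1004 genes. DESeq2 and limma voom called 0 in both. Without WT CBD replicate 1 the unadjusted counts were 1344 and 2168, and for Fmr1 KO 1141 without Fmr1 KO vehicle replicate 6 and 416 without WT vehicle replicate 4. Both contrasts subtract the effect in the same 12 WT libraries, so what they share is not independent, and no value without a change was computed for it. Ribosomal protein genes, lower with CBD in WT mice, were higher in 68 of 69 for Fmr1 KO (median 0.20, camera adjusted p = 2.11e-11; adjusted p = 0.892 with an estimated correlation) and in 67 of 69 for Shank3 KO mice (median 0.16, adjusted p = 5.31e-06; adjusted p = 0.962 with an estimated correlation). The ribosomal median for Fmr1 KO was 0.30 without Fmr1 KO vehicle replicate 6. Myelin genes were lower in 19 of 19 in each (medians -0.63 and -0.36; adjusted p = 0.892 and 0.962 with an estimated correlation), and for Shank3 KO by -0.23 and not called without Shank3 KO CBD replicate 6 (0.0801), by -0.19 without WT CBD replicate 6 and by -0.55 without WT vehicle replicate 5. The dentate list differed by a median of 0.64 in Shank3 KO mice (adjusted p = 2.75e-07; adjusted p = 0.798 with an estimated correlation). No list of either contrast passed that way.

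The mean CBD effect over the 3 genotypes was computed after seeing the data. Lcn2 rose by 2.74 (SE 0.363, adjusted p = 3.37e-05). S100a8 and S100a9, which encode the subunits of calprotectin, an abundant neutrophil protein, rose by 2.31 (SE 0.458, adjusted p = 0.0430) and 2.37 (SE 0.453, adjusted p = 0.0409). Vwf rose by 0.59 (SE 0.107, adjusted p = 0.0409). Levels of Lcn2 were low, at 0.966 ± 0.980 CPM (SD, n = 6) in WT CBD against 0.164 ± 0.143 in WT vehicle mice, 0.622 ± 0.613 against 0.0598 ± 0.0863 in Fmr1 KO and 0.688 ± 0.684 against 0.108 ± 0.113 in Shank3 KO mice. Vwf stood at 22.1 ± 5.24 CPM in WT CBD against 12.3 ± 3.43 in WT vehicle mice, where its fold was above the mean over genotypes. The count was 4 higher and 0 lower, with 670 genes at an unadjusted p under 0.05, 9 calls by DESeq2 and 6 by limma voom. Apold1 came next (0.53, SE 0.108, adjusted p = 0.117).

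That count of 4 changed with the settings more than the folds did. Over the settings and left-out libraries Lcn2 ran from 2.5 to 2.99, Vwf from 0.54 to 0.66, S100a9 from 2.11 to 2.77 and S100a8 from 2.02 to 2.60. The count was 0 under the strict filter and without the sex term, where Lcn2 had an adjusted p of 0.0591, and 1 with the replicate block. Lcn2 alone was called without WT vehicle replicate 2, 3, 4 or 6, WT CBD replicate 3, Fmr1 KO vehicle replicate 1, 2, 3 or 5, Fmr1 KO CBD replicate 4 or 6, Shank3 KO vehicle replicate 1, 4, 5 or 6, or Shank3 KO CBD replicate 3 or 4. The count was 2 without WT CBD replicate 2 or 6, Fmr1 KO vehicle replicate 4, Fmr1 KO CBD replicate 5, or Shank3 KO CBD replicate 2 or 5. Lcn2 was called without each of the 36 libraries in turn, Vwf in 15 of these fits, S100a9 in 14 and S100a8 in 11.

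As lists, the mean CBD effect was higher for glucocorticoid response genes in 22 of 24 (median 0.10, camera adjusted p = 9.72e-08; adjusted p = 0.0972 with an estimated correlation), with Fkbp5 at 0.20 and Nfkbia at 0.24. Microglial genes were higher in 11 of 12 (adjusted p = 5.59e-05; adjusted p = 0.565 with an estimated correlation), with C1qa at 0.20 and Ctss at 0.21, and 3 passed when adjusted over the list alone. Immediate early genes were higher in 27 of 33 (adjusted p = 8.96e-06; adjusted p = 0.565 with an estimated correlation) and inflammation genes in 17 of 19 (adjusted p = 0.000108; adjusted p = 0.565 with an estimated correlation), with Icam1 at 0.40. Erythrocyte genes, with Slc4a1 at 0.67 and Hbb-bt at 0.71, were called higher (median 0.53, adjusted p = 0.0421; adjusted p = 0.565 with an estimated correlation) but in 13 of 36 fits without a library. Ependymal genes were lower in 13 of 13 (median -0.33, adjusted p = 2.29e-08; adjusted p = 0.565 with an estimated correlation) and myelin genes in 19 of 19 (median -0.16, adjusted p = 1.05e-05; adjusted p = 0.728 with an estimated correlation). Of 46 lists camera called 17, with 12 higher and 5 lower, and only a part of them is given here. The myelin median was -0.08 without Fmr1 KO CBD replicate 3 and -0.09 without Fmr1 KO vehicle replicate 4, and that of inflammation genes 0.09 without Fmr1 KO CBD replicate 6.

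**Figure D4:**
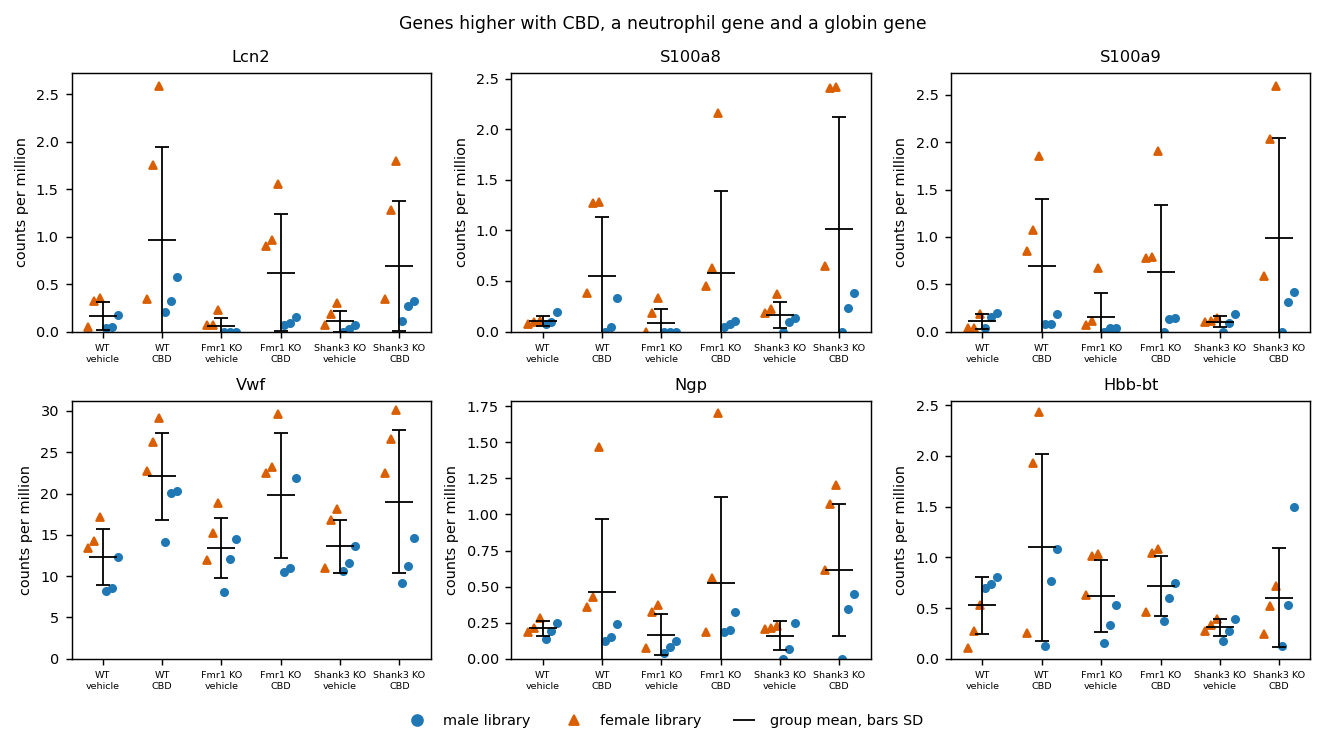
Level of Lcn2, S100a8, S100a9 and Vwf in CPM for each library, by group (n = 6), with the mean and SD (bars stop at 0). Lcn2 averaged 0.966 in WT CBD against 0.164 in WT vehicle mice, and Vwf 22.1 against 12.3.

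Males and females received different doses, so a difference between them mixes sex with dose. In the 9 CBD females over the 3 genotypes, Lcn2 averaged 1.28 CPM against 0.181 in 9 vehicle females, and in males 0.236 against 0.0400. S100a9 averaged 1.39 CPM in CBD against 0.162 in vehicle females, and 0.149 against 0.0826 in males. Vwf averaged 25.8 ± 3.23 CPM (SD, n = 9) against 15.2 ± 2.76 in females and 14.8 ± 4.83 against 11.1 ± 2.35 in males. In females S100a9 (3.27, SE 0.529, edgeR adjusted p = 0.00376), S100a8 (2.95, adjusted p = 0.0282) and Lcn2 (2.83, adjusted p = 0.00376) rose. In males, 0 genes passed in edgeR. At an unadjusted p under 0.05 there were 1476 genes (6.97%) in males and 651 (3.07%) in females. The difference between the sexes was not past the threshold for S100a9 (-2.31, SE 0.938, adjusted p = 0.659) or Vwf (-0.37, SE 0.209, adjusted p = 0.659). It is not given for Lcn2 and S100a8, since a group of males had no count and no SE could be computed. These means over genotypes were chosen after seeing the data.

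Within single genotypes, no gene passed in edgeR for the CBD effect in males, in females or in their difference. The counts at an unadjusted p under 0.05 were 804 in WT males, 1352 in WT females, 906 in Fmr1 KO males, 246 in Fmr1 KO females, 1659 in Shank3 KO males and 384 in Shank3 KO females. DESeq2 made 5 calls over these contrasts and limma voom 0. Without WT vehicle replicate 4, edgeR called 2 genes in WT males, and it called 1 gene for a difference between the sexes without WT CBD replicate 3 and without Shank3 KO vehicle replicate 2. Endothelial genes were higher in WT males given CBD in 15 of 15 (median 0.54, camera adjusted p = 1.12e-17; adjusted p = 0.0147 with an estimated correlation), and 9 passed when adjusted over the list alone. This compares 3 libraries with 3, with endothelial scores of 3.91, 3.88 and 3.67 against 3.35, 3.37 and 3.16 with vehicle. Males of the KO lines showed no such rise, with 3.33 to 3.91 given CBD and 3.55 to 3.80 given vehicle. Choroid plexus genes moved with them in WT males (17 of 17 higher, median 2.02; adjusted p = 0.460 with an estimated correlation). The endothelial list's difference between WT males and females had an adjusted p of 9.43e-07 in camera (adjusted p = 0.483 or more with an estimated correlation).

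Among CBD-treated mice, each KO line was compared with WT again in libraries independent of the vehicle groups. Ide rose by 1.04 (adjusted p = 1.25e-16) in Fmr1 KO and by 1.06 (7.81e-17) in Shank3 KO mice. Btaf1 rose by 0.78 and 0.80, and Fgfbp3 by 0.94 and 0.91. Fmr1 fell by 0.81 (adjusted p = 1.75e-08) in Fmr1 KO and Shank3 fell by 0.67 (adjusted p = 0.00781) in Shank3 KO mice. Pkdrej, a gene 44 protein-coding genes from Shank3 on chromosome 15, fell by 1.51 (adjusted p = 0.00213) in Shank3 KO mice. Under vehicle Pkdrej was also lower, at 0.750 CPM in Shank3 KO against 1.47 in WT mice, but was not called in the main fit. The totals were 5 higher and 2 lower in Fmr1 KO mice, with 1567 genes at an unadjusted p under 0.05, and 5 higher and 4 lower in Shank3 KO mice, with 350. For Fmr1 KO the unadjusted count was 2979 without WT CBD replicate 1, 994 without replicate 6 and 964 without replicate 3. For Shank3 KO it was 717 without WT CBD replicate 1, 535 without replicate 5 and 579 without Shank3 KO CBD replicate 2. ENSMUSG00000120174 and ENSMUSG00000131195 rose in both lines, while ENSMUSG00000139902 and ENSMUSG00000127813 (-1.30, adjusted p = 0.0141) fell in Shank3 KO mice. Under vehicle ENSMUSG00000127813 averaged 0.554 CPM in Shank3 KO and 1.07 in WT mice, without a call. Shank3 (-0.66, adjusted p = 0.266) and, in Fmr1 KO mice, Fgfbp3 (0.94, 0.0841) lost their calls in the compared groups alone, as did ENSMUSG00000139902 (0.146) and ENSMUSG00000127813 (-1.32, 0.0606) in Shank3 KO mice. ENSMUSG00000131195 was not called by DESeq2 in Shank3 KO mice (0.0783).

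Tmprss6, a protease that controls hepcidin, fell by 0.80 (SE 0.158, adjusted p = 0.0465) in Fmr1 KO mice given CBD. The call was lost in 8 of 12 alternatives and without 10 of the 12 compared libraries. Adjusted p was 0.0899 without WT CBD replicate 1, 0.268 without replicate 3, 0.181 without replicate 4, 0.127 without replicate 5 and 0.0524 without replicate 6. It was 0.0515 without Fmr1 KO CBD replicate 2, 0.147 without replicate 3, 0.212 without replicate 4, 0.188 without replicate 5 and 0.256 without replicate 6. ENSMUSG00000127813 lost its call without WT CBD replicate 2 and without Shank3 KO CBD replicates 2, 5 or 6 (largest adjusted p = 0.109), and without the 3 libraries farthest out on principal components (0.0578).

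Myelin genes were lower in Fmr1 KO than in WT mice given CBD, in 19 of 19 (median -0.72, camera adjusted p = 3.26e-19; adjusted p = 0.665 with an estimated correlation), and 18 passed when adjusted over the list alone. Ribosomal protein genes were higher in 69 of 69 (median 0.23, adjusted p = 5.73e-20; adjusted p = 0.665 with an estimated correlation) and oxidative phosphorylation genes in 37 of 39 (adjusted p = 1.99e-07; adjusted p = 0.665 with an estimated correlation). These 3 calls were kept without each of the 12 compared libraries. Striatal markers were called lower (median -1.80, adjusted p = 0.00888; adjusted p = 0.670 with an estimated correlation) but not without WT CBD replicate 3 (-0.57, 0.423) or 6 (0.0606) or Fmr1 KO CBD replicate 5 (0.0606). The choroid plexus call (median -1.62, adjusted p = 0.670 with an estimated correlation) was lost without WT CBD replicate 1 (0.0691). Of 46 lists camera called 14 for Fmr1 KO mice given CBD, with 8 higher and 6 lower, and only a part is given here. The CA1 score averaged 6.13 in Fmr1 KO CBD and 5.76 in WT CBD libraries, and the interneuron score 5.18 and 5.03. In Shank3 KO mice given CBD, interferon genes were lower in 23 of 25 (median -0.14, adjusted p = 0.000581; adjusted p = 0.628 with an estimated correlation), by -0.21 without WT CBD replicate 2. The dentate list was called higher (median 0.23; adjusted p = 0.705 with an estimated correlation) but not without WT CBD replicate 2 (0.10, 0.161) or Shank3 KO CBD replicate 5 (0.05, 0.0768).

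**Figure D5:**
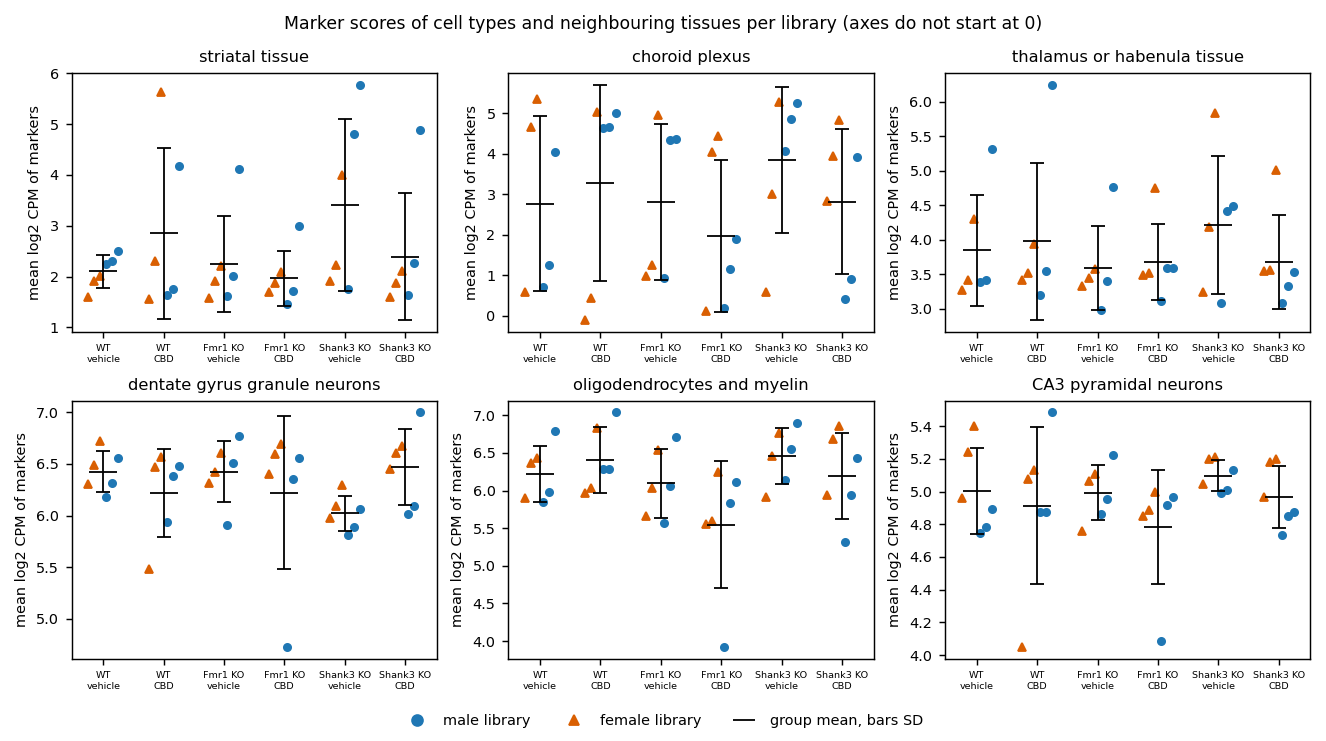
Marker score, the mean log2 CPM of a list's genes, for each library by group (n = 6), with the mean and SD. Striatal markers averaged 3.41 ± 1.69 in Shank3 KO vehicle and 2.85 ± 1.68 in WT CBD mice.

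Whether CBD moved the genotype differences back towards WT was asked from genes called under vehicle. For the 6 genes of Fmr1 KO mice, the fold changes under CBD regressed on those under vehicle with a slope of 1.29 (SE 0.0985), above the 0.900 to 1.12 of datasets without a CBD effect. ENSMUSG00000120174 (3.03 under vehicle, 3.90 under CBD) and ENSMUSG00000131195 (2.89 and 3.91), which had 41 and 3 counts in all WT CBD libraries together, were farther from 0 under CBD. The other 4 genes were close to their vehicle values or nearer to 0, with Ide at 1.15 and 1.04, Btaf1 at 0.83 and 0.78, Fgfbp3 at 0.90 and 0.94 and Fmr1 at -0.85 and -0.81. For the 8 genes of Shank3 KO mice the slope was 1.08 (SE 0.0543), within the simulated 0.870 to 1.13. CBD moved 3 of the 6 and 4 of the 8 genes against the genotype difference, where simulation gave 16.7% to 100% and 12.5% to 87.5%. Among the 200 genes with the smallest p, 90.5% moved against it in Fmr1 KO and 95.5% in Shank3 KO mice. Since the KO vehicle libraries enter both values, 40 datasets without a CBD effect gave 86.5% to 96.5% and 90.0% to 96.0%. These datasets held genotype differences in the called genes alone, so smaller real differences have no part in these ranges. Whether CBD reversed such differences cannot be read from them. With the KO vehicle libraries divided between the comparisons the shares averaged 45.6% and 66.4%, within ranges of 30.5% to 57.5% and 46.0% to 75.5%. Without a CBD effect, moves against and along the genotype difference would be about equally likely in this division. The 20 values per line reuse the same libraries, so their range does not measure an error. The slopes over these 200 genes were 0.235 (SE 0.0385) in Fmr1 KO mice, above the simulated 0.0541 to 0.230, and -0.114 (SE 0.0396) in Shank3 KO mice, below the simulated -0.0196 to 0.357. Genotype fold changes under vehicle and under CBD share no library. Over 21172 genes they correlated at r = 0.00987 in Fmr1 KO and -0.261 in Shank3 KO mice. No value without a change was computed for these correlations. Genes are not independent replicates in these values. The simulated datasets drew each gene independently, without the correlation between genes of the real libraries. Their ranges can therefore be too narrow, and a slope outside them does not show an effect of CBD.

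Sex differences under vehicle gave a check of the labels. The Y-linked genes Kdm5d (8.70), Ddx3y (7.56), Uty (8.88) and Eif2s3y (9.23) were higher in males, and their X-linked partners Ddx3x (-0.37, adjusted p = 0.000229), Kdm5c (-0.40, adjusted p = 0.000263) and Eif2s3x (-0.59, adjusted p = 0.00322) were lower. These 7 were all the calls of edgeR and of DESeq2, with 581 genes at an unadjusted p under 0.05. Limma voom called 11 genes, and the strict filter, which removes the Y-linked genes, left 3. As lists, genes that escape X inactivation were lower in 6 of 6 (median -0.42; adjusted p = 3.95e-10 with an estimated correlation). Ddx3y ran from 40.7 to 64.7 CPM in males and from 0.102 to 1.15 in females.

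The genes fixed for every main comparison did not pass in any. Cnr1, the main cannabinoid receptor of brain, was at 0.05 and 0.12 in Fmr1 KO and Shank3 KO vehicle mice. With CBD it was at -0.11, 0.07 and -0.20 in WT, Fmr1 KO and Shank3 KO mice. Single libraries raised the CBD means of the KO lines. Its log2 CPM was 8.44 in Shank3 KO CBD replicate 6, against 7.22 to 7.58 in the others. In Fmr1 KO CBD replicate 5 it was 8.33, against 7.59 to 7.79. Gpr55, a receptor that CBD blocks, was at -0.09 and 0.24, and at 0.14, 0.34 and -0.67 with CBD, the last with an unadjusted p of 0.0194 and an edgeR adjusted p of 0.963. The oxytocin receptor gene Oxtr was at -0.22 and -0.09, and at -0.32, 0.50 and -0.07 with CBD. Its log2 CPM was 3.61 in Shank3 KO CBD replicate 6, against 1.38 to 2.20 in the others, which raised that mean. In Fmr1 KO CBD libraries Oxtr ran from 2.94 to 15.2 CPM around a mean of 6.46. Grm5, the glutamate receptor gene central to fragile X studies, was at 0.15 and 0.22, and at 0.08, 0.04 and -0.13 with CBD. The growth factor gene Bdnf was at 0.00 and -0.20, and at -0.12, -0.06 and 0.23 with CBD. With SEs of 0.141 to 0.378 for these genes, small changes were not detectable with this number of animals. Whether depth added to this was not tested.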

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

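The tests of a library difference between WT and KO mice, of loss of Fmr1 alone, of a DNA segment, of neutrophils and of gene bodies were chosen only after the results were seen, as was the mean CBD effect.

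Ide, Btaf1 and Fgfbp3 were higher in both KO lines. A technical difference between WT and KO libraries would spread over many genes, but only 5 genes were called in the same direction in all 4 comparisons of a KO line with WT. Loss of Fmr1 alone would leave Shank3 KO mice at the WT level, yet the median size of the log2 difference between the KO lines in these genes was 0.0466. Besides Ide, 2 called genes lie within 5 protein-coding genes of it, which was seen before that distance was set. A difference in the DNA of a segment of chromosome 19 is a candidate explanation, but Cpeb3 and March5, which lie between these genes, were not called. The animal codes began with the same letters in 11 of 12 WT and in all Fmr1 KO libraries and with others in Shank3 KO libraries. The letters therefore do not part WT from both KO lines. The code numbers do part the genotypes, with 13, 14 and 17 in these WT libraries and 12, 15 and 16 in Fmr1 KO libraries. What letters and numbers stand for is not given, so the codes do not decide on the origin of the mice. The genetic backgrounds were not given in the sources used here and DNA was not analysed here, so an effect of each mutation through a shared path stays open.

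Lcn2, S100a8, S100a9 and Vwf were higher with CBD over the 3 genotypes. Carried-over choroid plexus, striatal or thalamic tissue is argued against, since with the tissue covariates 101% of the median increase and 4 calls were left. With the erythrocyte covariate, for blood left in the tissue, 89.0% of the increase and 2 calls were left, with Lcn2 at 2.5 and Vwf at 0.63; S100a9 (2.13, adjusted p = 0.191) and S100a8 (2.03, adjusted p = 0.214) lost theirs as the folds fell slightly, so that blood cannot be told apart for them. More neutrophils in the tissue or its vessels could contribute, since the 6 genes of the 20-gene neutrophil list that were measured besides the called ones were higher as a set, with a median of 0.47 and a rotation test (fry, limma) p = 0.000398 (n = 36 libraries). Against this, 33.3% of them reach 1 CPM, and Csf3r (0.08) and Hdc (0.04) hardly moved. Induction of Lcn2 and Vwf in vessel cells was not tested.

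Of 928 list members in the table, 58 had no count in any library, among them B2m, Olig2, Sox9 and Jun, which brain expresses. Reads from several copies are argued against for most of them, since a median of 97.8% of their 50-base stretches occur in no other gene. Over 80% of the stretches were unique in 45 of the 58. The share was lower in the globin genes Hba-a2 (10.7%) and Hbb-bs (46.8%), so several copies stay open for these. Counting over whole gene bodies, with reads in overlapping bodies dropped, is a candidate explanation for part of the 58 genes. Of the 58, 46.6% lie mostly inside another gene's body, against 5.17% of the members with counts (Fisher exact p = 3.13e-17). Overlap of most exon bases with exons of other genes was also more frequent (12.1% against 0.805%, Fisher exact p = 6.34e-06), but it covered only 7 of the 58. The other 31 genes stay unexplained by overlap in the older annotation, and overlap with newer gene models was not examined. Any gene listed at 0 was left out of its list.

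Chance regrouping was tested with 100 splits for each count. For Fmr1 KO against WT under vehicle, only the real split (1 of 100) reached 6 genes and the highest other gave 0. The real split also stood alone for Shank3 KO under vehicle (1 of 100, real 8, highest other 1) and under CBD (1 of 100, real 9, highest other 3). It did so for the sex difference too (1 of 100, real 7, highest other 5). A share of 1 of 100 is the lowest that these splits can give. The counts include genes that differ by design, the targeted gene or, for sex, the Y-linked genes and their X-linked partners. These splits therefore speak about the counts and do not secure any other single call. For Fmr1 KO under CBD, 4 of 100 splits reached the real 7 and the highest other gave 568. For the mean CBD effect, 4 of 100 reached the real 4 and the highest other gave 1603. What sets apart the splits that called many times the real count was not tested, and these small counts are not secured by a share under 0.05. A real count of 0 is reached by 100 of 100 splits whatever the data, so for these results the splits say nothing about chance. The highest other counts were 178 for the CBD effect in WT mice, 0 in Fmr1 KO and in Shank3 KO mice, 103 and 1625 for the difference in effect of Fmr1 KO and Shank3 KO from WT, and 22 for the effects per sex.

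Single libraries stood far from the other 5 of their group in 25 of 258 tests, where chance gives about 1 in 20, or 12.9. The value given is the gap to the nearest library over the range of the group. Total counts of Shank3 KO vehicle replicate 2 were low (0.752), and so was Dennd6b in that library (0.833). Fmr1 KO CBD replicate 3 had the lowest CA3 (0.842), dentate (0.83) and myelin (0.701) scores of its group. Fmr1 KO vehicle replicate 4 had a low score of newborn neurons (0.811) and high thalamic (0.665) and striatal (0.750) scores. Thalamic scores were high in WT CBD replicate 6 (0.756), Fmr1 KO CBD replicate 6 (0.708) and Shank3 KO CBD replicate 1 (0.757), and the striatal score in Shank3 KO CBD replicate 2 (0.795). The mural score of Fmr1 KO CBD replicate 5 was high (0.642) and the meningeal score of WT CBD replicate 4 low (0.721). In Shank3 KO CBD replicate 6, Fmr1 was low (0.798) while Cnr1 (0.71) and Oxtr (0.631) were high. Cnr1 was high in Fmr1 KO CBD replicate 5 (0.728), Gpr55 in Fmr1 KO vehicle replicate 1 (0.734), Shank3 in Shank3 KO vehicle replicate 6 (0.653) and S100a8 in WT vehicle replicate 1 (0.638). ENSMUSG00000120174 was high in Shank3 KO CBD replicate 4 (0.655), ENSMUSG00000127813 in WT CBD replicate 2 (0.640) and Fmr1 KO vehicle replicate 4 (0.673), and Tmprss6 low in WT vehicle replicate 6 (0.669).

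Gene lists whose CBD effect differed between genotypes by camera are given with the adjusted p of the difference. In Fmr1 KO minus WT, lower lists were those of myelin (2.11e-10), endothelium (3.13e-05), mural cells (0.00979), choroid plexus (0.0157) and striatum (0.0157), and higher lists those of the unfolded protein response (0.000926), heat shock (0.000261), oxidative phosphorylation (0.000261) and ribosomal proteins (2.11e-11). In Shank3 KO minus WT, higher lists were those of dentate neurons (2.75e-07), postsynaptic scaffolds (0.0497) and ribosomal proteins (5.31e-06). Lower lists there were those of myelin (0.00188), endothelium (0.000307), mural cells (0.00552), choroid plexus (0.00370), thalamus (0.0243), striatum (6.80e-06) and interferon genes (0.00857). With an estimated correlation none passed (adjusted p of 0.874 or more and 0.798 or more). In the 24 fits without a library, the calls least often kept were those of choroid plexus (11) and striatum (19) for Fmr1 KO, and of postsynaptic scaffolds (14) and thalamus (18) for Shank3 KO.

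Lists whose CBD effect differed between males and females, who had different doses, were these. Each sex of a group held 3 libraries, and these list calls were not tested without single libraries. In WT mice the effect was higher in males for CA3 neurons (0.00770), endothelium (9.43e-07), choroid plexus (9.65e-09), ependyma (7.73e-05), cholesterol synthesis (0.00146), Nrf2 targets (0.00662), the unfolded protein response (0.0322) and antigen presentation (0.00492). It was lower for CA1 neurons (0.0297), neocortex (0.0111), glutamate receptors (0.00157), clock genes (0.00249) and mitochondrial messengers (0.000265). In Fmr1 KO mice it was higher for oligodendrocyte precursors (0.00937), early genes (0.000559), cholesterol synthesis (0.00153), the unfolded protein response (0.00937) and ribosomal proteins (0.00128). It was lower for dentate neurons (0.00262), myelin (0.00213), choroid plexus (1.96e-06), ependyma (0.0245) and interferon genes (0.0367). Fmr1 KO CBD replicate 3, a male, had a dentate score of 4.73 against 6.35 to 6.69 in the rest of its group. Its myelin score was 3.92 against 5.55 to 6.25, so the dentate and myelin entries can rest on that library. The Y-linked list also differed (0.000118), through few counts in Fmr1 KO females, with CBD most of them in replicate 6, and is not given as an effect of CBD. In Shank3 KO mice it was higher for interneurons (0.000513), astrocytes (0.0289), FMRP targets (0.0184), cholesterol synthesis (0.0235), oxidative phosphorylation (0.0168), ribosomal proteins (0.0168) and presynaptic genes (0.0168). It was lower for myelin (0.000460), meninges (1.05e-05), choroid plexus (1.26e-11), ependyma (1.05e-05), Nrf2 targets (0.0321), xenobiotic metabolism (0.0322), interferon genes (0.0119), antigen presentation (0.0168) and mitochondrial messengers (0.0168). None passed with an estimated correlation (smallest adjusted p of 0.483, 0.480 and 0.594).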

How the results depend on the processing

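The covariates of tissue and erythrocyte markers, every setting of the mean CBD effect, leaving out libraries for gene lists and the slope over 200 genes without the target's chromosome were chosen after seeing the data. Of single named genes under all settings, 8288 values kept their direction and side of the threshold, 112 lost a call, 5 gained one, 153 of uncalled genes changed sign and 0 of called genes did. With the compared groups alone, calls were 4 for Fmr1 KO and 5 for Shank3 KO against WT under CBD; fewer libraries enter that fit. The strict filter, which tests fewer genes, left 4 for Fmr1 KO under CBD, 3 for the sex difference and 0 for the mean CBD effect. DESeq2 called 9 for the mean CBD effect and 5 for the effects per sex, and limma voom 1 for CBD in Shank3 KO mice and 11 for the sex difference. The mean CBD effect had 0 calls with no sex term, 1 with the replicate block and 2 with the erythrocyte covariate; the cause was not tested. Replicate numbers gave little sign of pairing, with a mean r of 0.0193 over 90 same-numbered pairs (smallest -0.419) and -0.00301 over 450 others. Still, 12 of 36 libraries matched best with their own number, a larger share than same-numbered pairs hold among all pairs. Weak pairing is therefore not excluded. The replicate block gave 9 calls for Shank3 KO under vehicle. Over the 9 planned comparisons without sex, list calls numbered 90, against 0 with an estimated correlation, 0 with fry, 74 to 86 under other settings and 74 to 103 without single libraries. These are totals, and the lists behind them changed. Of the 12 lists called for CBD in Shank3 KO mice, 4 stayed called with 1 surrogate variable and 5 with the tissue covariates. Of the 12 for CBD in WT mice, 10 and 8 stayed, and of the 11 in Fmr1 KO mice, 9 and 9. Among the sex contrasts, 1 list in WT males and 2 in the sex difference also passed with an estimated correlation and fry. Slopes for Fmr1 KO mice were 0.235 over 200 genes, 1.48 without the X chromosome and 0.219 over 200 genes without it. For Shank3 KO mice they were -0.114 over 200 genes and -0.138 without chromosome 15, against 1.08. Leaving out single libraries gave 6 calls throughout for Fmr1 KO under vehicle, 7 to 12 for Shank3 KO under vehicle, 6 to 8 and 8 to 11 under CBD, 1 to 5 for the mean CBD effect, 7 to 8 for sex, 0 to 2 for effects per sex and 0 for CBD within genotypes and for their differences. Lcn2, S100a8 and S100a9 average under 2 CPM, where depth limits precision.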

Other observations

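All values in this part were examined after the data had been seen. Correlations of the CBD effect between genotypes were small across 21172 genes. They were -0.0979 between WT and Fmr1 KO mice, -0.229 between WT and Shank3 KO mice and 0.195 between the KO lines. Values as far from 0 came from 61, 19 and 29 of 100 splits, the real one included. Genes are not independent replicates in such a correlation.

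Neutrophil genes beyond S100a8, S100a9 and Lcn2 had these mean CBD effects. Ngp, a granule protein gene, was at 1.41 (SE 0.327), Ltf, which encodes lactoferrin, at 0.77 (SE 0.467) and Retnlg at 0.69 (SE 0.265). Mmp9 was at 0.25 (SE 0.147), Csf3r at 0.08 (SE 0.0655) and Hdc at 0.04 (SE 0.182). None passed in the main fit, where Ngp had the smallest edgeR adjusted p, 0.195. Ngp averaged 0.844 CPM in 9 CBD females against 0.233 in 9 vehicle females, and 0.226 against 0.126 in males.

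Genes of the Y chromosome had a few counts in females, and carry-over of reads between libraries was not tested. In Fmr1 KO females given CBD all 4 had higher values than with vehicle (median 1.49, camera adjusted p = 9.74e-06; adjusted p = 0.193 with an estimated correlation), and 3 passed when adjusted over the list alone. Replicate 6 held most of these counts, with Ddx3y at 1.15 CPM against 0.524 and 0.484 in the other 2 females of that group and 40.7 or more in every male, so the difference is not given as an effect of CBD. Xist, which females express from the inactive X chromosome, had 204 counts over all 36 libraries; its gene overlaps that of its antisense partner Tsix.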
